A study of Homo sapiens with 8 samples.

How the data were processed

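H3K27me3 is trimethylation of lysine 27 on histone H3, a mark written by the Polycomb repressive complex 2, whose catalytic subunit is EZH2. It was measured by chromatin immunoprecipitation and sequencing in SK-N-AS cells, a neuroblastoma cell line, after 14 days with vehicle or with 1 uM tazemetostat, an EZH2 inhibitor. The labels list 8 samples, made up of 2 H3K27me3 libraries and 2 input libraries per treatment. The series' design text speaks of a larger number of biological replicates than the labels give for this assay. Nothing in the labels says which libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The deposited table has no columns for the 4 input libraries, and inputs were not analysed here. Libraries were grouped by their titles. The treated columns carry the abbreviation EPZ, read as the code name EPZ-6438 of tazemetostat, the only drug in the labels.

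Per the submitters' processing notes, the tools were Bowtie2 2.3.5, Picard 2.18.2, deepTools, MACS2, ChIPseeker and DESeq2, with the human build GRCh38 (hg38) and the fly build dm6. The notes give neither the role nor the order of these tools. Per the labels' protocols, Drosophila chromatin was added to each immunoprecipitation as a spike-in. The deposited table holds 88858 regions that do not overlap each other, with a median width of 2254 bp and a range from 251 to 669510 bp. Region starts are counted from 0 in the table and are given here counted from 1.

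The deposited table gives the counts of reads per region for each library, not normalized. It also gives a signal, named AUC per the file headers, which is a summed coverage over the region on a scale that the authors set for each library. Within a library the AUC was close to a constant multiple of the count, with a coefficient of variation between 2.86% and 3.91% over regions with many counts. The constant was 444 and 576 AUC units per count in vehicle replicates 1 and 2, and 127 and 92.9 in tazemetostat replicates 1 and 2. How the authors set this constant, and whether from the spike-in, is not given in the sources used here. All statements about levels between treatments rest on it. The deposited log2 columns hold log2(AUC + 1), within rounding to 2 decimals, and a pooled column per treatment. The authors' deposited table also holds a DESeq2 comparison with a log2 fold change, a p-value and an adjusted p-value per region. Its base mean was recovered within 0.068% from the counts with size factors computed from the counts in these regions, so that comparison is relative to the typical region and not on the AUC scale. A deposited score of -1, 0 or 1 marks regions as lower, neither or higher, and deposited 0 or 1 columns say whether a peak was called in each library and in the pooled libraries of each treatment, per the file headers.

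The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(AUC + pseudocount) of the 4 H3K27me3 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount was 1746 AUC units, 0.1 times the median positive value. Fold changes are on this log2(AUC + pseudocount) scale, which understates the change of low regions. The libraries were not centred further, because centring would remove a shift shared by all regions. The design fixed before the data were examined foresaw either a normalized signal or counts. The table held both, so the signal was tested as written there, and edgeR 4.0.16 (quasi-likelihood test, TMM factors) on the counts was added as a relative comparison, which asks whether a region changed more or less than the typical region. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333.

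The table names genes for some regions only. Regions were therefore assigned to each of the 19375 protein-coding genes of the RefSeq annotation of GRCh38 whose extent, widened by 2.5 kb on both sides, they overlapped. This replaced a window around transcription start sites, since the annotation table used gives no strand. In all, 10287 genes had a region, and 37224 regions lay at a gene. A gene's value was the mean of the log2 values of its regions, and AUC and counts printed for a gene are sums over its regions. A broad region can hold several genes, which then share 1 value. For 1804 genes, the only region held another gene too. The 14 gene lists were fixed before the data were examined and tested with fry (whether members move 1 way on balance) and camera (whether members differ from other genes, with a preset correlation of 0.01 and with an estimated one). The named genes followed a rule fixed at the same time: ST8SIA1, up to 4 called members per list with the largest change, and the 10 largest falls and rises among called genes above the median level whose libraries did not overlap between treatments. Other genes and regions named, such as list members that rose or were not called, were chosen after their values were seen.

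On simulated counts for the 88858 regions, with 200 changed and no other difference between treatments, limma recovered 33 of 34 regions lowered 8-fold, 26 of 33 lowered 2-fold and 25 of 33 raised 2-fold. It called 2 of the 88658 regions that had not been changed, and edgeR called 6. Alternatives covered the scaling, pseudocount, filter on low regions, a replicate block, leaving out each library, width, the choice of regions per gene, and the count tests, DESeq2 1.42.0 included. Data were prepared with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.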

Results

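The data comprised 4 H3K27me3 libraries of SK-N-AS cells, 2 from cells kept with vehicle and 2 from cells treated with 1 uM tazemetostat for 14 days. Counts in the 88858 deposited regions were 93681119 and 77802283 in vehicle replicates 1 and 2, and 43763097 and 44073595 in tazemetostat replicates 1 and 2. AUC values of regions and genes are given in kilo-units (k) and library totals in giga-units (G). The median count per region was 202, 167, 51 and 50 in the same order. The single comparison in the design was tazemetostat against vehicle. It addressed where the mark is lost under EZH2 inhibition, with attention in the labels to ST8SIA1, which encodes GD3 synthase, an enzyme on the path to the ganglioside GD2.

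H3K27me3 fell across the genome with tazemetostat. Total AUC in the regions was 43.2 ± 2.27 G (SD, n = 2) with vehicle and 4.82 ± 1.03 G (SD, n = 2) with tazemetostat, an 8.96-fold difference. The median region kept 4.48% of its vehicle AUC, with quartiles of 2.86% and 7.86%. The difference between the treatments in the library median of log2 AUC was -3.76, against SDs of 0.06 with vehicle and 0.25 with tazemetostat (n = 2 each). Of 88858 regions, limma called 81145 (91.3%) lower and 2803 (3.15%) higher, and 4910 were not called. In 81718 regions both tazemetostat libraries lay below both vehicle libraries, and in 3235 both lay above. Chance gives 16.7% for each on average, but regions share the scale of their library and tend to be ordered together. These counts are therefore not a test over regions. The 8.96-fold difference includes a 4.64-fold difference in the authors' AUC per count, while counts themselves differed 1.95-fold, and an error in that scale would move all regions together. With the libraries centred on their medians, limma called 32263 regions lower and 31610 higher.

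**Figure D1:**
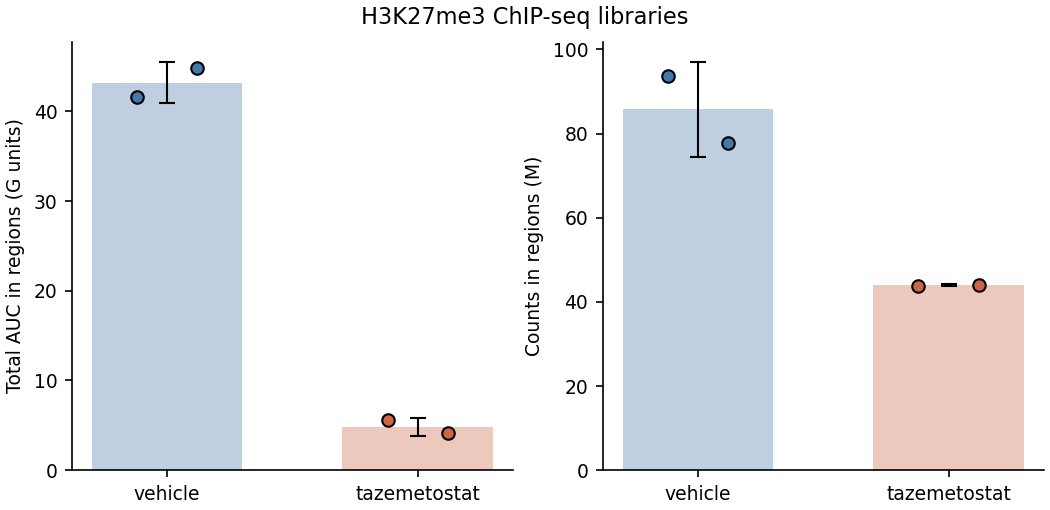
Total AUC (left, G units) and counts (right, M for mega) in the 88858 regions for each H3K27me3 library, shown as points, with bars for group means and error bars for the SD (n = 2). Total AUC was 41.6 and 44.8 G with vehicle and 5.55 and 4.10 G with tazemetostat.

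At ST8SIA1 (GRCh38, chromosome 12, 22193391 to 22334707), H3K27me3 fell in each of 12 regions. AUC summed over them was 7402 ± 266 k (SD, n = 2) with vehicle and 203 ± 38.8 k (SD, n = 2) with tazemetostat, so that 2.74% remained. The gene-level log2 change was -4.51 (SE 0.24, limma adjusted p = 6.4e-75), and counts were 16308 and 13270 with vehicle against 1906 and 2003 with tazemetostat. A region that the deposited annotation classes as promoter, 22242627 to 22268806, lies within the gene's extent. It fell from 1776 ± 129 to 32.6 ± 3.06 k AUC units (SD, n = 2), a log2 change of -5.69, and 1.84% remained. Another region of this class within the gene, 22269946 to 22291578, kept 2.38%. The region of this class that spans the gene's boundary at 22334707, 22327252 to 22343557, kept 3.22%. It was the 1 region of the 12 with a peak called in the pooled tazemetostat libraries. The smallest fall was in an intronic region of 267 bp, with a log2 change of -2.27. Relative to the typical gene, ST8SIA1 as a whole also lay lower by edgeR on counts, with a log2 change of -1.21 (adjusted p = 8.0e-10). That call was common, as the same test called 5170 of 10287 genes lower and 4144 higher. Relative to the typical region, edgeR called 7 of the 12 regions lower and 1, an intronic region from 22210555 to 22214944, higher (0.58, adjusted p = 0.0065), and 4 were not called. All 12 regions were called by limma when adjusted over the gene alone, 8 with median-centred libraries and 7 with quantile normalization.

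**Figure D2:**
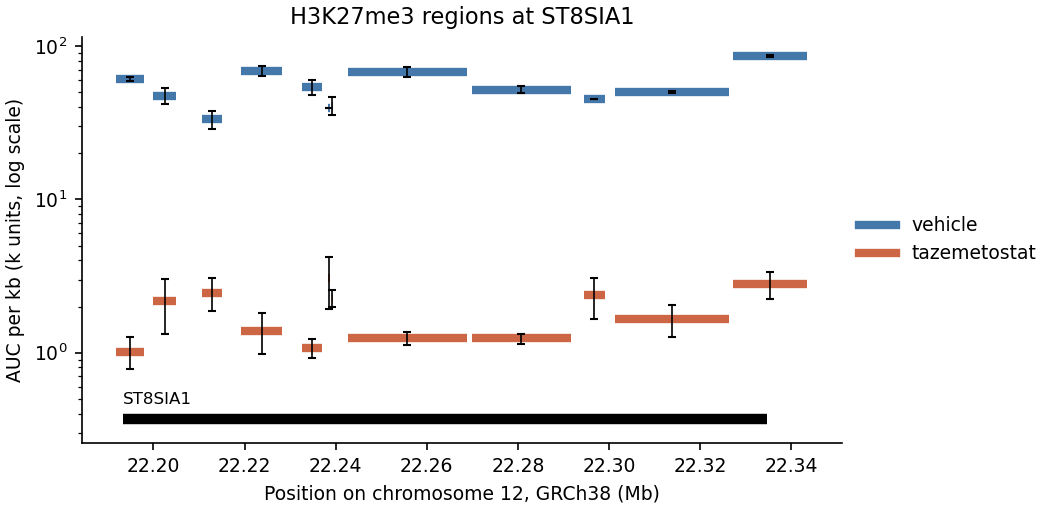
AUC per kb (k units, log axis) of the 12 regions at ST8SIA1 along chromosome 12 (GRCh38, Mb), with horizontal bars for the mean of 2 libraries over each region's extent and vertical bars for the SD. The black bar is the gene. Each tazemetostat mean lies below its vehicle mean, with log2 changes from -5.69 to -2.27.

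Of 12 genes with a region in the ganglioside list, which holds synthesis genes along with ABCA4, ARSA and GLB1, 11 fell and none rose, and the counts were 11 and 0 when adjusted over the list alone. ARSA, which encodes a lysosomal sulfatase, fell by 5.55 on the log2 scale, from 265 ± 16.9 to 3.94 ± 0.02 k (SD, n = 2). ST3GAL5, which encodes GM3 synthase, changed by -4.71 and kept 2.72%. ABCA4, which encodes a retinal transporter, changed by -4.70. The list's median log2 change was -3.78, set beside -3.72 over all genes tested. ST3GAL1 was the member not called, with a log2 change of -0.11 over the mean of its regions and -1.84 (limma adjusted p = 2.7e-10) over their summed AUC.

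Over all 10287 genes with a region, limma called 8285 (80.5%) lower and 1094 (10.6%) higher, and 908 were not called. The largest falls were at MEIS3, a homeobox gene (log2 change -7.05, SE 0.25), RING1, a core component of Polycomb repressive complex 1 (-7.01, SE 0.28), and FH, which encodes fumarate hydratase (-6.94, SE 0.26). Next came ABHD4 (-6.91), HIGD2B (-6.89), SAP18 (-6.86), UNC50 (-6.81) and TAMALIN (-6.80). C14orf119 and CIROP, at -6.72, shared 1 region. The region at RING1 fell from 6932 ± 407 to 52.3 ± 8.54 k AUC units (SD, n = 2), and 0.755% remained. The limma adjusted p of these 10 genes was at most 8.3e-132. These p-values rest on a spread pooled over genes that share the scale of each library. With median-centred libraries limma called 4229 genes lower and 4508 higher.

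The largest rise was at ZFP36L1, which encodes an RNA-binding protein of mRNA decay. Its AUC went from 20.0 ± 0.986 to 428 ± 97.2 k (SD, n = 2), a log2 change of 4.29 (SE 0.25, limma adjusted p = 1.4e-63). Counts there were 50 and 35 with vehicle and 3831 and 3812 with tazemetostat. The zinc finger genes ZNF436 (log2 change 2.68), ZNF134 (2.52), ZSCAN29 (2.34), ZSCAN2 (2.33) and ZNF12 (2.31) were also among the 10 largest rises, with SSBP1 (2.55), AJUBA (2.54), TACC3 (2.46) and CHD2 (2.21). At ZNF12, AUC was 137 ± 31.9 k with vehicle and 700 ± 277 k with tazemetostat (SD, n = 2). The number of genes called higher by limma was 620 without tazemetostat replicate 1, against 1094 with all libraries.

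Developmental regulators kept the most H3K27me3 among the large lists. The 35 HOX genes with a region, homeobox genes that pattern the body axis, lay in 5 regions. The HOXB cluster lay in the widest region tested (chromosome 17, 48131805 to 48801314, 669510 bp), which also held SKAP1, TTLL6, PRAC1 and PRAC2. This whole region went from 245865 ± 14797 to 127391 ± 26651 k AUC units (SD, n = 2), and 51.8% remained. HOXB1, HOXB2 and HOXB3 shared this region and had a gene-level log2 change of -0.96 (SE 0.29, limma adjusted p = 0.0011), which was not called without vehicle replicate 1 (-1.02, limma adjusted p = 0.15) or without vehicle replicate 2 (-0.90, limma adjusted p = 0.20). The HOXA cluster (chromosome 7, 27080136 to 27230965), chosen after its values were seen, held 69141 ± 4334 k with vehicle and 97585 ± 19600 k with tazemetostat (SD, n = 2), a log2 change of 0.48 (limma adjusted p = 0.17), which was called higher in the gene-level limma test without tazemetostat replicate 2 (0.69, adjusted p = 0.012). HOXD1 lay in a region of its own and fell by 4.88. In all, 20 HOX genes fell, none rose and 15 were not called, and the counts were 20 and 0 when adjusted over the list alone.

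Of 79 other developmental transcription factors, 51 fell, none rose and 28 were not called, and 49 fell when adjusted over the list alone. Their median log2 change was -1.11, and the median member kept 51.5% of its vehicle AUC. By the mean of log2 values over a gene's regions, the largest falls were at NKX6-1 (-5.70), GATA4 (-5.02), PAX5 (-4.63) and LHX8 (-3.99). Over summed AUC, PAX5 kept 17.8% and LHX8 9.97%, so the rank of both depends on this choice. Relative to the typical gene, PAX5 lay higher by edgeR on counts (1.41, adjusted p = 1.2e-11). Among members chosen after their values were seen, PAX6 held 109% of its vehicle AUC (log2 change 0.11) and DLX1 and DLX2, which shared a region, 92.0% (-0.13), and none of these was called. Relative to other genes, camera placed the HOX list (adjusted p = 4.2e-08) and the developmental transcription factors (adjusted p = 2.5e-06) higher. With an estimated correlation (0.997 and 0.89) the camera adjusted p was 0.96 for both, as for every other list. That version called no list under any setting, so it could not tell lists apart. The preset 0.01 lies far below these estimates, and how far the first p-values hold was not tested. With median-centred libraries the list medians were 2.85 and 2.65, and with quantile normalization 0.069 and 1.23, so their direction against vehicle depends on the scale.

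Lists of neuroblastoma cell states both fell for the most part, as did most genes tested. Camera separated neither list from other genes (adjusted p = 0.57 for both). Of 25 adrenergic genes with a region, 22 fell and 2 rose, with a median log2 change of -4.39. The neurofilament gene NEFM (-6.27), GATA3 (-5.24), HAND1 (-5.18) and the monoamine transporter gene SLC18A1 (-5.09) fell most. ISL1, which encodes a transcription factor of sympathetic neurons and was chosen after its value was seen, rose by 0.70. It was not called by limma without vehicle replicate 1 (0.64, adjusted p = 0.38) or without vehicle replicate 2 (0.77, adjusted p = 0.29). Of 25 mesenchymal genes, 20 fell and 4 rose, with a median of -3.24. SNAI2 (-5.75), a factor of epithelial-mesenchymal transition, THY1 (-5.10), IL6 (-4.91) and NOTCH2 (-4.87) fell most, while VIM, which encodes vimentin, rose by 1.06 and SOX9 by 0.84, the latter not called by limma without vehicle replicate 1 (0.59, adjusted p = 0.34) or without vehicle replicate 2 (1.10, adjusted p = 0.071). The counts were the same when adjusted over the list alone. With median-centred libraries the mesenchymal median was 0.52.

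Immune recognition genes fell in most cases, as did 80.5% of all genes tested. Camera separated neither list from other genes (adjusted p = 0.67 for antigen presentation and 0.85 for natural killer ligands). Of 29 antigen presentation genes listed, 15 had a region. Among these 13 fell and 1 rose, with a median log2 change of -4.28. HLA-DMA and HLA-DMB, which load peptides on class II molecules and shared a region, fell from 23431 ± 1330 to 370 ± 89.4 k (SD, n = 2). HLA-E changed by -4.74 and HLA-DPA1 by -4.68. All 17 ligands of natural killer cells with a region fell, CD276 (-5.64), CLEC2D (-4.98), CD48 (-4.12) and TNFRSF10A (-3.86) the most, with a median of -3.40. The counts were the same when adjusted over the list alone. With median-centred libraries the median of the natural killer list was 0.35.

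Of 12 cell cycle inhibitors and tumour suppressors, 9 fell and 2 rose. CDKN2A and CDKN2B, neighbouring genes for inhibitors of CDK4 and CDK6, fell by 6.50 and 6.23 (limma adjusted p = 2.4e-132 and 1.4e-139). NGFR changed by -5.59 and CHD5 by -4.04, while RB1 rose by 0.76. Of 13 genes of the Polycomb complexes, 8 fell and 3 rose: RING1 (-7.01), BMI1 (-5.56), CBX7 (-5.43) and EPOP (-4.30) fell most, and MTF2 (2.05), AEBP2 (1.56) and RBBP4 (0.73), all of them partners of Polycomb repressive complex 2, rose. RB1 and RBBP4 were not called by limma without vehicle replicate 1 (adjusted p = 0.13 and 0.054), vehicle replicate 2 (0.15 and 0.31) or tazemetostat replicate 1 (0.21 and 0.26). Of 30 housekeeping genes, 3 had a region. PSMB2 fell by 5.76, while RAB7A rose by 2.16 and SDHA by 1.35, the latter from counts of 10 and 13 with vehicle to 217 and 163. The counts of these lists were the same when adjusted over the list alone.

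All 25 haematopoietic genes with a region fell (median log2 change -4.10), such as GATA1 (-6.23), CD3E (-5.79), LYZ (-5.77) and CD3D (-5.26). All 19 hepatocyte genes fell (median -4.53), among them HNF4A (-5.77), AHSG (-5.61), and FGA and FGB (-5.43), which shared a region. By camera these lists lay lower than other genes (adjusted p = 0.031 for each), and with an estimated correlation the adjusted p was 0.96. With each region counted once, the camera adjusted p was 0.083 for the haematopoietic and 0.0014 for the hepatocyte list, and 0.98 for both with an estimated correlation. Of 12 Schwann cell and melanocyte genes, 10 fell and none rose, such as NGFR (-5.59), ERBB3 (-4.94) and TYR (-4.53). Of 26 genes of synapses and channels, 25 fell, such as SYN1 (-5.80), SNAP25 (-5.14), KCNC1 (-4.48) and SYP (-4.47), and 1, SYT1, rose by 1.00, which was not called by limma without vehicle replicate 2 (adjusted p = 0.071) or without tazemetostat replicate 1 (adjusted p = 0.31). The counts of these lists were the same when adjusted over the list alone.

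**Figure D3:**
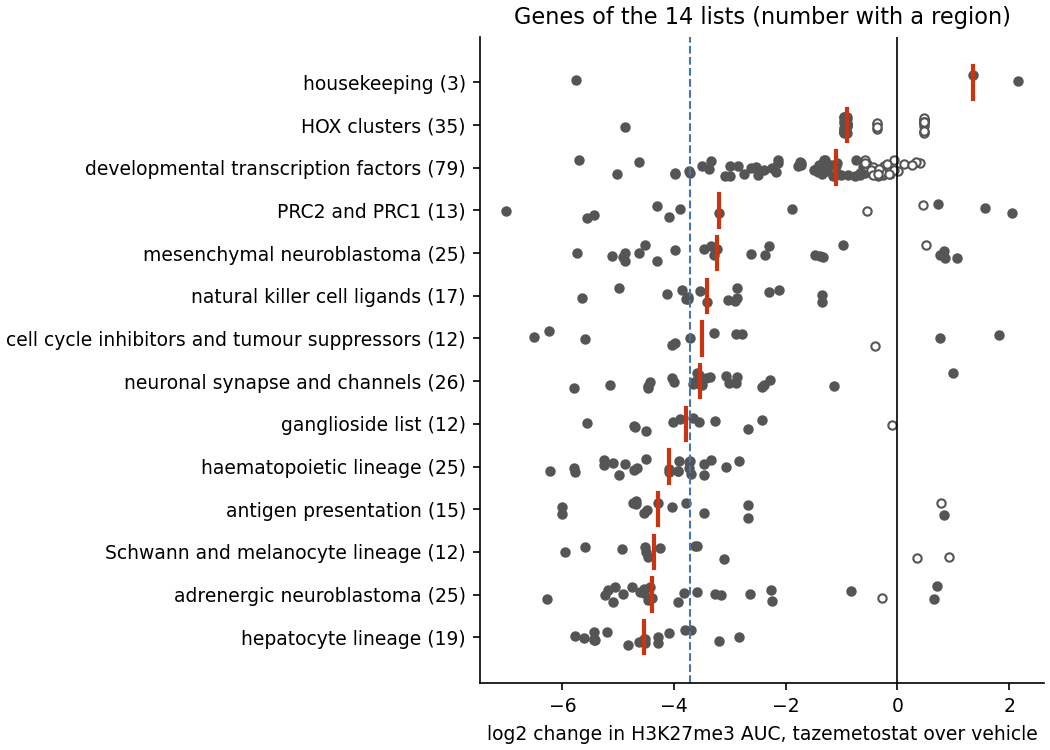
Gene-level log2 change in AUC, tazemetostat over vehicle, for the genes of 14 lists (rows, with the number of genes that had a region). Filled points passed limma's threshold and open points did not, red bars are list medians, and the dashed line is the median of all genes (-3.72). The HOX list (median -0.90) and the developmental transcription factors (-1.11) lie to the right of that line.

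By fry, 12 of the 14 lists moved lower on balance, with adjusted p-values from 0.0056 to 0.021. The HOX and housekeeping lists did not pass (adjusted p = 0.13 for both). Fry asks about change from vehicle, and 80.5% of all genes tested were called lower. Its direction was therefore nearly fixed by the genome-wide fall and says little about single lists. Camera with the preset correlation, which sets a list against other genes, called 4 of the 14. With each region counted once, the HOX list passed (adjusted p = 0.029 by fry and 0.016 by camera). The housekeeping list was then called higher than other regions by camera (adjusted p = 0.0012). With an estimated correlation camera called neither, but its adjusted p was 0.98 for all 14 lists, so it could not tell them apart. No list was called by fry without vehicle replicate 1 or without vehicle replicate 2. The housekeeping list had a positive median (1.35) and a negative mean (-0.75). For natural killer ligands, cell cycle inhibitors and synapse genes, the median lay above that of all genes while camera's direction was lower, and camera called none of these 3.

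Region classes differed in the size of the fall on the main scale, by an amount that depended on the pseudocount. The median log2 change was -4.38 in 5' UTR regions, -4.34 in 3' UTR regions, -4.22 in exons and -4.11 in promoters, against -3.66 in distal intergenic regions and -3.42 in introns. With a pseudocount of 0.01 times the median, 5' UTR regions had -4.62 and introns -4.27, and with AUC per kb -4.11 and -3.87. The median AUC that remained was between 3.70% (3' UTR) and 4.86% (introns) in these classes. Regions with little AUC fell less on this scale, with medians of -2.53 in the lowest quartile of mean AUC and -4.68 in the highest, while the median AUC that remained was 6.79% and 3.65%. With median-centred libraries, introns (0.34) and distal intergenic regions (0.10) had positive medians.

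Peak calls in the deposited table fell from 77271 regions in pooled vehicle libraries to 22369 in pooled tazemetostat libraries. The 66489 regions with a peak in vehicle alone were all called lower by limma and kept a median of 3.71% of their AUC. Peaks were called on the same libraries that limma tested, so this direction was nearly fixed in advance. The 10782 regions with a peak in both were broad (median width 9848 bp), lay at promoters in 40.5% of cases and kept 7.71%. A further 11587 regions had a peak in pooled tazemetostat alone. They were narrow (median 695 bp), lay in introns in 45.5% of cases and had a median log2 change of -0.15. Of this set 4002 regions (34.5%) were called lower and 2790 (24.1%) higher, out of 2803 called higher in all. The set was picked by peaks in these same libraries, which favours rises in it. When a peak was required in both tazemetostat libraries and in neither vehicle library, the set held 3203 regions. The number called higher was 1074 without tazemetostat replicate 1.

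Relative to the typical region, edgeR on the counts called 24281 regions lower and 27229 higher. The authors' deposited table marks 23787 regions lower and 3874 higher, and its median log2 fold change is -0.02, while its median pooled log2 AUC difference is -4.49. Its marks were cut on the same AUC, with a pooled log2 difference of at most -4.58 in regions marked lower and at least 0.50 in those marked higher. That limma on AUC called all 23787 of the former and 2795 of the latter in the same direction was therefore nearly fixed.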

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

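Alternatives on the count tests with the AUC scale, on peaks in both replicates and on regions used once were chosen after the data were seen. Of 994 values of the 73 genes chosen by rule under the alternatives, 980 kept their direction and call, and of 319 values of 24 genes named after their values were seen, 239 did, while 28 turned, 27 lost their call and 25 gained one. The cause of the changes below was not tested, except that filters leave fewer regions and genes to call and that centring and quantile normalization set the median change to 0. Input-subtracted values were not run, since inputs were not analysed here.

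With median-centred libraries, 32263 regions were lower and 31610 higher, 4229 genes lower and 4508 higher, and the median change was 0.00. Introns (0.34), distal intergenic regions (0.10), HOXB1, HOXB2 and HOXB3 (2.79 each) and the medians of the mesenchymal (0.52), HOX (2.85), developmental (2.65), natural killer (0.35), cell cycle (0.25), Polycomb (0.57) and synapse lists (0.22) turned positive, as did ST3GAL1 (3.65), DLX1 and DLX2 (3.62), UNCX (3.01), NR5A2 (2.14), ZIC1 and ZIC4 (3.18), PAX2 (2.67), HOXD10, HOXD13 and EVX2 (3.38), NKX2-1 (3.32), LHX2 (3.41) and NXN (2.75). With quantile normalization, 34334 regions were lower and 21892 higher, 4857 genes lower and 3929 higher, the median change was 0.00, 7 ST8SIA1 regions were called, and the mesenchymal (0.26), HOX (0.069), developmental (1.23), cell cycle (0.043) and Polycomb lists (1.10) turned positive, as did ST3GAL1 (2.55), DLX1 and DLX2 (1.78), UNCX (0.55), NR5A2 (0.49), ZIC1 and ZIC4 (0.97), PAX2 (0.29), HOXD10, HOXD13 and EVX2 (1.30), NKX2-1 (1.22), LHX2 (1.62) and NXN (0.39).

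The median log2 change was -4.12 with a pseudocount of 0.01 times the median and -2.24 with 1 times the median, where camera called 2 lists. Above the 25th percentile, 836 regions and 279 genes were higher, the median change was -4.10, camera called 2 lists and the housekeeping median was -1.80. Above the median, 44150 regions changed (43963 lower, 187 higher), 5048 genes changed (4972 lower, 76 higher) and the median change was -4.37. AUC per kb gave 1728 regions higher. Promoter regions alone gave 441 genes higher, 2 lists called by camera and a haematopoietic difference from all genes of 0.017.

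With a replicate block, 80777 regions were lower and 2577 higher, fry called 0 lists and camera 2. The numbers do not pair the samples, as deviations of same-numbered libraries had a correlation of -0.02. Leaving out 1 library, which assumes that a lone library varies like the others, gave 1074 to 2727 regions higher, 620 to 1258 genes higher, total AUC changes from -3.40 to -2.96 (log2), 0 to 12 lists called by fry and 2 to 4 by camera.

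Relative regions by edgeR were 64561 lower and 14179 higher with library totals, 80665 and 2050 with the AUC scale, and 15176 and 15273 above the median, and DESeq2 with the AUC scale gave 79429 and 952. Peaks in both replicates numbered 50064 with vehicle, 10274 with tazemetostat and 3203 with tazemetostat alone. Depth limits the low regions, with median counts of 51 and 50 per region in the tazemetostat libraries.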

Other observations

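Of the tests below, those on background reads, promoters and the authors' scale were chosen after the results were seen, as was the family of zinc finger genes. H3K27me3 left after tazemetostat was concentrated in few regions. The 100 regions with the most AUC held 33.5% of all tazemetostat AUC, while the 100 with the most vehicle AUC held 10.5% of vehicle AUC, and 54 regions were in both sets. The 30 regions with the most tazemetostat AUC kept between 23.1% and 141% (the HOXA cluster) of their vehicle AUC. Among them, chosen after their values were seen, were those of UNCX (60.1% of vehicle AUC remained), NR5A2 (69.0%), ZIC1 and ZIC4 (67.6%), PAX2 (47.5%), HOXD10 to HOXD13 with EVX2 (77.9%), NKX2-1 (74.5%) and LHX2 (79.4%). Not all lay at developmental regulators, as NXN (50.4%) and 2 regions on unplaced or unlocalized scaffolds (57.3% and 34.0%) were also in this set.

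Zinc finger genes, taken by symbol and so with ZFP36L1 among them, were called higher by limma in 123 of 442 cases (27.8%) and lower in 202. Of 9845 other genes, 971 (9.86%) were called higher (Fisher's exact test, two-sided, p = 4.4e-25, with genes that neighbour each other not independent). Genes were tested only where a peak was called in these same libraries. Of regions called higher, 99.5% had a peak in pooled tazemetostat alone. Such a region lay at 64.3% of zinc finger genes and 15.2% of other genes, so the p-value is no independent support. The median log2 change was -0.36 for the zinc finger genes, against -3.78 for other genes. The count was 62 without vehicle replicate 1 and 79 without vehicle replicate 2, and with median-centred libraries 379 were higher and 38 lower. On chromosome 19, which carries many of these genes, 988 of 2413 regions (40.9%) had a peak in pooled tazemetostat alone, against 12.3% elsewhere, and 562 of the 988 lay at a zinc finger gene.

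The first pattern weighed is the AUC kept at developmental regulators. Over 129 regions with a vehicle peak at genes of the HOX and developmental lists, the median log2 change was -2.13. That the regions are broad and strongly marked is argued against as the whole cause, since 10000 sets of regions matched on width and vehicle AUC per kb had medians between -4.40 and -3.40. Median tazemetostat counts per kb were 19.4 times those of regions with a peak in vehicle alone (705 against 36.2, both libraries summed). The latter were picked for having no tazemetostat peak, which lowers their density. Over all regions the median was 22.8 and 22.1 counts per kb in tazemetostat replicates 1 and 2. The counts thus argue only against reads spread evenly, and they hold the same reads as the kept AUC. Background that differs between regions was not tested. A response of these regions to EZH2 inhibition itself stays open and was not tested.

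The second pattern is the rise at 123 of 442 zinc finger genes, a minority of the family. Background at active promoters is left open. Of 302 regions at zinc finger genes that limma called higher, 48.3% lay outside promoters and 5' UTRs. Of the 1023 regions at these genes not called higher, 56.3% did, so the called regions did not lie outside more often. Promoters alone held 42.1% of the called and 41.2% of the other regions. The called regions lay more often in 5' UTRs (9.60% against 2.54%) and 3' UTRs (21.9% against 10.5%). They lay less often in introns (19.5% against 33.2%) and exons (5.96% against 7.14%). Of the 121 called among regions above the median AUC only 25.6% lay outside. The 302 regions became 166 without vehicle replicate 1 and 187 without tazemetostat replicate 1. Olfactory receptor genes, another family of close copies, had a median log2 change of -4.24 and none of 296 called higher by limma. Being close copies therefore did not by itself go with a rise. Whether reads from some zinc finger copies were counted at others cannot be told from this, since that family held no rise to spread. For the family, whether AUC rose or was only kept cannot be told apart from an error in the authors' scale. The median log2 change of all 442 genes was -0.36, within the 2.22 that separates the AUC per count of the treatments, while its distance from the -3.78 of other genes is larger than the 0.45 that separates the tazemetostat libraries. No biological explanation is put forward for the excess of these genes over others, and binding of the antibody to another mark was not tested, with tazemetostat-only regions at -0.37 on 96 scaffold regions and -0.14 on chromosomes.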
